A study of Mus musculus with 2 samples.

How the data were processed

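The data came from 2 Illumina mouse bead arrays, 1 hybridised with RNA of all cells dissociated from E11.5 hearts and 1 with RNA of the lacZ-positive epicardial cells isolated from such hearts. Both samples came from mice that carry lacZ at the Tcf21 locus, on a mixed background of C57BL/6, 129 and CD-1, per the labels. On a bead array each probe sits on many beads, and the brightness of its beads after hybridisation measures the amount of the matching RNA. RNA was extracted with the miRNeasy Mini Kit and checked on a Bioanalyser, and biotin-labelled cRNA was made with the MessageAmp kit of Ambion, per the labels' protocols. GenomeStudio was used, per the submitters' processing notes, which give no version. The genome build and the authors' normalization method are not given in the sources used here.

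The main table held, per the file headers, the mean bead intensity of each of 45281 probes on each array, as deposited by the authors. Checked on the values, these intensities were on a linear scale, were not background-subtracted, with a lowest value of 31.0 on the total heart array and 34.1 on the lacZ-positive array, and were not scaled between the arrays. The standard error of that intensity over beads and the number of beads per probe also stood in the deposited table, per the file headers. A detection p-value per probe was deposited too, per the file headers, and the p-values were multiples of 1/936. This step is that of a share of 936 control probes that were as bright as the probe or brighter. A second table, in the series matrix, held intensity values processed by the authors. Their sorted columns differed by at most 0.1406%, their medians were 58.3 for both arrays, and the rank correlation of each column with the unprocessed column of the same array was 1. Those values were therefore on a linear scale, equalised between the arrays and not centred. The brightest of them was 48745.22 where the mean of the brightest values of both arrays was 49752.36, so that plain averaging of sorted values did not give them, and the method by which they were made stayed unknown. No column of per-sample values was left out.

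Probes were named through GEO's platform annotation. Of the 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none in that table. Probes with several symbols or none were not named. The gene identifiers of 34807 named probes were found in a RefSeq gene table of the mouse, and 0 of their symbols differed from it. The named probes stood for 19057 gene symbols. Gene coordinates were not printed, because no genome build is stated for the array.

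The following choices were made before the data were examined. Intensities were corrected for background with the normexp model, with background mean and spread estimated from the detection p-values (nec in limma 3.58.1, R 4.3.3). An offset of 16 was added, and the arrays were quantile-normalized and put on the log2 scale. A probe counted as detected at a detection p-value under 0.01, and a gene was analysed if a probe of it was detected on at least 1 array. A gene with several detected probes was represented by the one with the highest mean log2 signal. The log2 ratio was the lacZ-positive value minus the total heart value, and genes were counted as higher or lower at a size of at least 2-fold. The error given beside a log2 ratio is the standard error over beads, carried to the log2 scale. It covers bead-to-bead error on these arrays only, not the spread between animals, isolations or hybridisations.

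Each group had 1 array, so no test between the groups was possible and no p-value, SD between replicates or replicate check is given. A gene detected on 1 array only has a bound, given as "at least N-fold". The bound is the brighter value against the higher of the dim probe's own value and the lowest value among detected probes of the dim array. Counts and list medians use the measured values of such genes, so a gene counted as past 2-fold can have a smaller bound, and list medians are given again with bounds where these differ by more than 0.1. For lists of genes, the median log2 ratio was set beside the medians of 10000 random lists of the same size, matched on mean log2 signal in 20 bins. The percentile describes these arrays and is not a p-value.

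The genes that could be named were set by a rule. It took Tcf21 first, then the 12 genes with the highest and the 12 with the lowest log2 ratio among genes detected on both arrays. It then took the 6 with the largest bound in each direction. Of every list it took the members with the 3 highest and the 3 lowest log2 ratios and any member past 2-fold. Transcripts known only by a clone name, a LOC name or a Gm name were counted but not described. The text gives examples from the genes so set.

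There were 30 lists. The 11 lists of cell type markers covered epicardium and mesothelium, cardiomyocyte sarcomere, cardiomyocyte calcium handling and excitation, endothelium and endocardium, erythroid cells, leukocytes with platelets, smooth muscle with pericytes, fibroblasts with epicardium-derived mesenchyme, endocardial cushion and valve mesenchyme, hepatoblasts with endoderm, and neural crest with neurons. The other 19 held cardiac transcription factors, retinoic acid genes, the C/EBP family, Hox genes, TALE factors, epithelial junctions and keratins, regulators of epithelial-to-mesenchymal transition, basement membrane and matrix, growth factors, complement and coagulation, interferon response, respiratory chain, fatty acid oxidation with the tricarboxylic acid cycle, glycolysis, cell cycle, ribosomal proteins, immediate early and stress genes, heme with hypoxia and unfolded protein genes, and sex-linked transcripts.

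The alternatives tried were no background correction, normexp without detection p-values at an offset of 50, an offset of 50, scaling to the same median, no normalization between arrays, and the authors' processed values. Further ones were a detection limit of 0.05, detection on both arrays, no detection filter, the mean of a gene's detected probes, and a size of 4-fold. A log2 ratio or list median counted as moved at a shift of more than 1.5 times, as did a count. Another alternative, the brightest detected probe under log2 14 on both arrays, was added after seeing the data.

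The steps were tested on simulated arrays with background and bead noise but no biological spread, with 200 genes changed by known folds among 9530 detected genes. For this comparison, a simulated 2-fold change was recovered with a median log2 ratio of 0.94, and 29.9% of such genes passed 2-fold. A simulated 4-fold change gave 1.93 and 98.5%, and an 8-fold change gave 2.86 and 100%. Of unchanged genes, 0.279% passed 2-fold, and 0 of 20 unchanged lists lay outside the central 95% of random lists. The simulated changes were few and balanced in direction, which favours quantile normalization, and labelling and hybridisation error were left out. These shares therefore give no rate of false calls on the real arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.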

Results

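Gene expression was measured at E11.5 in all cells dissociated from the mouse heart and in the lacZ-positive epicardial cells isolated from it. E11.5 is a day of gestation in the middle of heart development, and the epicardium is the cell layer that covers the heart. The hearts carried lacZ at the locus of Tcf21, a transcription factor gene used as a mark of epicardium and its derivatives. Each group had 1 array, and this number limits the precision of every value: no difference given here has a replicate check, and differences are described by size only. The median raw intensity was 57.6 on the total heart array and 63.5 on the lacZ-positive array, over a median of 43 beads per probe on each. The bead standard error had a median of 4.44% of the intensity for detected probes on the total heart array and 4.48% on the lacZ-positive array. In the total heart array 15553 of 45281 probes (34.3%) were detected, for 9147 named genes. In the lacZ-positive array 16226 probes (35.8%) were detected, for 9336 named genes. Of the 9713 genes detected on at least 1 array, 8770 were detected on both, 377 on the total heart array only and 566 on the lacZ-positive array only.

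The comparison asks which transcripts were more or less abundant in the sample of lacZ-positive epicardial cells than in that of the heart as a whole. Tcf21 itself, read by 1 detected probe, was 2.53-fold higher in the lacZ-positive cells, with a log2 ratio of 1.34 and a bead standard error of 0.079. Where that probe lies relative to the part of the gene replaced by lacZ is not known here, so its value checks neither the allele nor the isolation. Markers of epicardium and mesothelium were higher in the lacZ-positive array, with a median log2 ratio of 1.57, and so were markers of mesenchyme. Markers of cardiomyocytes and of erythroid cells were lower, with medians of -1.57 for the sarcomere and -2.09 for erythroid cells. Markers of endothelium lay close to level, at a median of -0.043. Cardiomyocyte and erythroid markers still gave signal on the lacZ-positive array. That array missed 0 of 24 detected sarcomere genes and 1 of 18 detected erythroid genes. It missed 5 of 21 for calcium handling and excitation. Among bright ones, Myl2 of the sarcomere had a log2 signal of 14.76 there and the erythroid Slc4a1 13.02. The share of RNA from other cells was not measured, so ratios compare samples and not pure cell types.

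In all, 371 genes were at least 2-fold higher in the lacZ-positive array and 626 were at least 2-fold lower. Of these, 290 of the higher and 452 of the lower genes were detected on both arrays. The other 81 higher and 174 lower genes were detected on 1 array only, and some of them have a bound under 2-fold. At 4-fold the numbers were 15 and 138. Higher genes thus made up 37.2% of the genes past 2-fold. This split depended on the scaling: with no normalization between arrays, 1020 genes were higher and 381 lower, or 72.8% higher, and the median log2 ratio of all genes was 0.42 in place of 0.044. The log2 values of the arrays had a Pearson correlation of 0.952 across the 9713 genes, which are not independent replicates. Probes of the same gene give a further view of the technical error: the log2 ratio differed between a pair of probes with an SD of 0.25 per probe over 2145 genes. Of the genes past 2-fold, 298 had over 1 detected probe, and 16 of them had a probe of the opposite sign that was detected on at least 1 array.

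**Figure D1:**
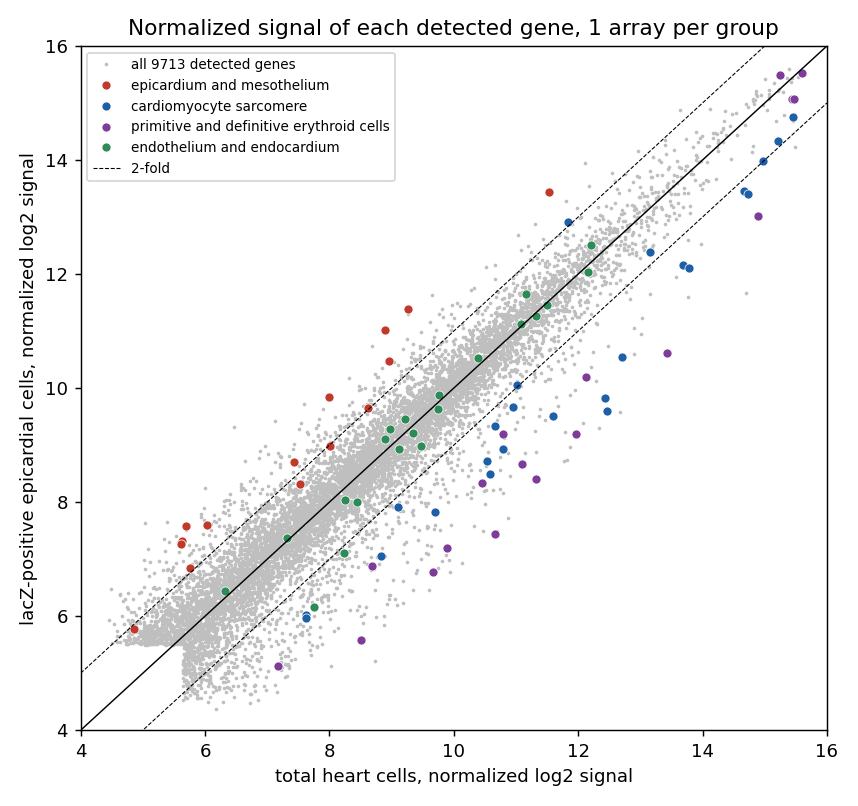
Normalized log2 signal of each of the 9713 detected genes in total heart cells (x axis) and lacZ-positive epicardial cells (y axis), 1 array each, with 4 marker lists in colour and dashed lines at 2-fold. Epicardial markers lie above the diagonal, most sarcomere and erythroid markers below it, and endothelial markers along it.

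The gene with the highest ratio among those detected on both arrays was Angptl7, an angiopoietin-like secreted protein gene, 7.18-fold higher by its chosen probe. Its other probe, not well above background in total heart, gave a log2 ratio of 1.39. Next came Sh3tc2 (4.94-fold), Il18 (4.74-fold), which encodes an interleukin, and Upk1b (4.37-fold), which encodes a uroplakin of epithelial surfaces. Tmem255a was 4.35-fold higher and Hpgd, whose product inactivates prostaglandins, 4.34-fold. Fads6, Psmb1, Ildr2, Ch25h, Tm4sf5 and Kcne1l completed the 12 genes, between 4.25-fold and 3.94-fold. Bead standard errors of these 12 log2 ratios lay between 0.059 and 0.20. Some of the 12 were dim in total heart, with log2 signals of 6.00 for Il18 and 6.47 for Angptl7, where the lowest detected signal was 5.65. Background weighs more on such ratios. Others were brighter, such as Kcne1l at 9.65. Among genes detected on the lacZ-positive array only, the largest bounds were those of Sowahd (at least 4.0-fold higher), Smpd3 (at least 3.96-fold), Btn1a1 (at least 3.38-fold), Edn2 (at least 3.28-fold), Lrrn4 (at least 3.18-fold) and Gsta3 (at least 3.14-fold).

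At the other end, Hemgn, which encodes a nuclear protein of blood-forming cells, had the lowest ratio among genes detected on both arrays, 9.32-fold lower. Icam4 (9.19-fold lower), Ermap (8.95-fold) and Kel (8.51-fold) encode proteins of the red cell surface, and Slc25a37 (8.54-fold), or mitoferrin, carries iron into mitochondria. Nppa, which encodes the atrial natriuretic peptide of cardiomyocytes, was 8.23-fold lower. Cyp4b1-ps2, Pdzk1ip1, Lmx1a, Cited4, Trim10 and Slc30a10 completed the 12, between 9.24-fold and 8.20-fold lower. Of genes detected on the total heart array only, Cfap57 was at least 9.44-fold lower and Sln, or sarcolipin, a regulator of the calcium pump in muscle, at least 5.73-fold. The bounds of Txlnb, Esrp1, Klhl31 and Kcnn4 lay between at least 4.94-fold and at least 4.60-fold lower.

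Of 22 epicardial and mesothelial markers on the array, 15 were detected, and 12 of these were at least 2-fold higher in the lacZ-positive array, 3 were within 2-fold and 0 were lower. Their median of 1.57 lay at percentile 100 of the random lists. Upk3b, a uroplakin gene of mesothelium, was 3.75-fold higher, Aldh1a1, which makes retinoic acid, 3.70-fold, and the keratin gene Krt7 3.60-fold. Bnc1 (2.86-fold), a zinc finger gene of epithelia, and Aldh1a2 (2.41-fold), the main retinoic acid synthesis gene of the embryonic epicardium, were also higher. The smallest measured ratio of the list was that of Krt19, at 0.79, and Dmkn, not well above background in total heart, was at least 1.09-fold higher. Wt1 and Tbx18, also members of the list and named outside the rule, were not among the 15 detected genes. They therefore have no ratio here. The list had 24 genes, and whether Wt1 and Tbx18 were among the 22 on the array is not stated here.

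**Figure D2:**
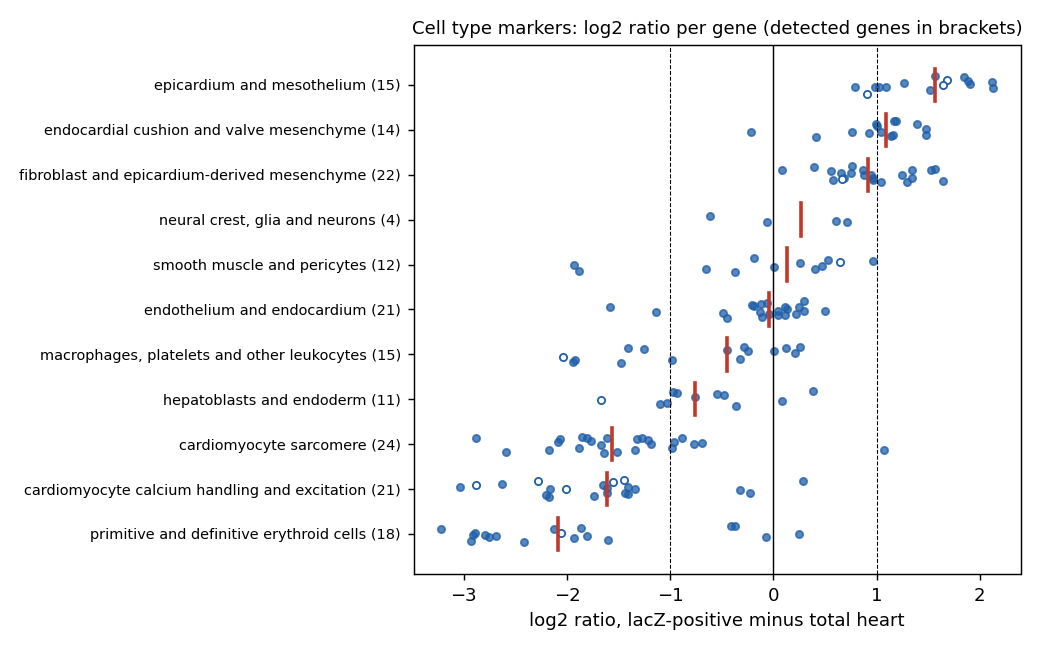
Log2 ratio, lacZ-positive minus total heart (x axis), of each detected gene in the 11 lists of cell type markers, with red bars at the list medians, dashed lines at 2-fold and open circles for genes detected on 1 array only. The epicardial list lies highest, at a median of 1.57, and the erythroid list lowest, at -2.09; the endothelial median of -0.043 is above 0 with no normalization between arrays.

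Cardiomyocyte genes were lower as a group. Of 24 detected sarcomere genes, 18 were at least 2-fold lower, 5 were within 2-fold and 1 was higher, with a median of -1.57 at percentile 0. The myosin genes Myl1 (7.35-fold lower) and Myh6 (6.04-fold) and the actin gene Acta1 (4.52-fold) had the lowest ratios, while the atrial light chain gene Myl7 stood at -0.77. The ventricular Myl2 stood at -0.69, by a probe with a log2 signal of 15.4 in total heart, near the top of the intensity range, where sizes are open to a ceiling. The exception was Tpm1, a tropomyosin gene also used outside striated muscle, which was 2.10-fold higher, and both of its detected probes were above 1. Of 21 detected genes of calcium handling and excitation, 18 were at least 2-fold lower, 3 were within 2-fold and 0 were higher, with a median of -1.61 at percentile 0. Nppb was 6.17-fold lower, the gap junction gene Gja5 4.61-fold and the calcium pump gene Atp2a2 3.05-fold, though another of the 3 probes of Atp2a2 gave -0.15. The 3 genes within 2-fold were Corin (-0.32), Gja1 (-0.23) and Gjc1 (0.29).

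Of 18 detected erythroid genes, 14 were at least 2-fold lower in the lacZ-positive array, 4 were within 2-fold and 0 were higher, with a median of -2.09 at percentile 0. Gfi1b and Nfe2, transcription factor genes of red cells and platelets, were 7.60-fold and 7.52-fold lower, and the heme synthesis gene Alas2 was 6.95-fold lower. The 4 within 2-fold were globin genes. Hba-x stood at -0.37, Hbb-bh1 at -0.41, Hbb-y at -0.075 and Hba-a1 at 0.25, where Hbb-bh1 was named after its value was seen. The probes that stood for these 4 genes were at the top of the intensity range, with normalized log2 signals above 14 on both arrays. Hbb-b2, with a dimmer probe, was 3.03-fold lower.

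**Figure D3:**
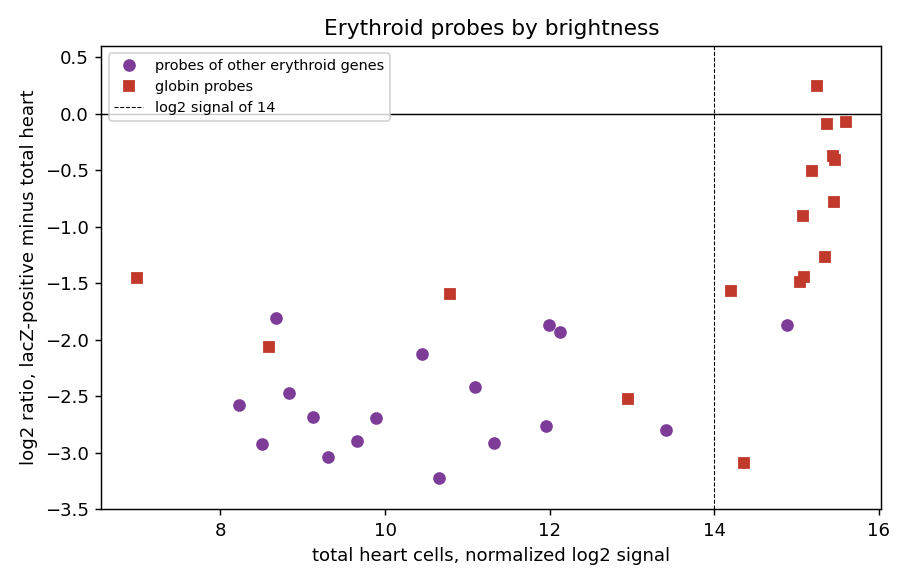
Log2 ratio, lacZ-positive minus total heart (y axis), against normalized log2 signal in total heart (x axis) for each probe of erythroid genes detected on both arrays, with globin probes as red squares and a dashed line at a log2 signal of 14. The 4 globin probes under that line lie between -2.52 and -1.45, and the 13 brighter ones have a median of -0.78 and run from -3.09 to 0.25.

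Of 21 detected endothelial genes, 19 were within 2-fold and 2 were lower, Cldn5 (log2 ratio -1.59) and Robo4 (-1.13). Their median of -0.043 lay at percentile 20.8 and became 0.34 with no normalization between arrays. Among 15 detected genes of leukocytes and platelets, 6 were at least 2-fold lower, 9 were within 2-fold and 0 were higher, with a median of -0.45 at percentile 0.15 that became -0.023 with no normalization between arrays. The 6 lower genes were the platelet genes Gp1bb (at least 3.30-fold), Ppbp (3.83-fold), Gp9 (3.78-fold), Pf4 (2.66-fold) and Itga2b (2.39-fold), and Lyz2 (2.79-fold), a lysozyme gene of macrophages. The macrophage gene Csf1r stood at 0.21. Smooth muscle and pericyte genes had 2 of 12 lower, Abcc9 (3.81-fold) and Cspg4 (3.70-fold), 10 within 2-fold and a median of 0.13 at percentile 72.8, which was -0.089 without the detection filter. In that list Acta2 stood at -0.66 by its brightest probe and at -1.59 by the lowest of its 4 detected probes. Of 11 detected hepatoblast and endoderm genes, 3 were lower and 8 within 2-fold, with a median of -0.76 at percentile 0.02. The lower ones were Foxa1 (at least 1.79-fold), Apoa2 (2.15-fold) and Apoa1 (2.04-fold). Only 4 genes of the neural crest and neuron list were detected, 0 of them past 2-fold, with a median of 0.27 at percentile 84.0 that became -0.61 at a detection limit of 0.05.

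Mesenchymal genes were higher in the lacZ-positive array. Of 22 detected genes of fibroblasts and epicardium-derived mesenchyme, 8 were at least 2-fold higher, 14 were within 2-fold and 0 were lower, and all 22 measured ratios were above 0, with a median of 0.92 at percentile 100. Loxl1, which crosslinks elastic fibres, was 3.14-fold higher, the proteoglycan genes Dcn and Ogn 2.96-fold and 2.88-fold, and Pdgfra 2.06-fold. Tcf21, the locus that carries lacZ, was another of the 8. Of 14 detected genes of endocardial cushion and valve mesenchyme, 9 were higher, 5 were within 2-fold and 0 were lower, with a median of 1.09 at percentile 100. Sox9 and Papss2, both of cartilage and valve formation, were each 2.79-fold higher, Has2, which makes hyaluronan, 2.63-fold, and Twist1 2.21-fold. Tbx2 was the only member below 0, at -0.21.

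Most detected members of the transcription factor families were within 2-fold. Of 22 detected cardiac transcription factors, 6 were at least 2-fold lower, 16 were within 2-fold and 0 were higher, with a median of -0.24 at percentile 0.86 that became 0.16 with no normalization between arrays. Those lower were Nkx2-5 (4.10-fold), Irx2 (3.60-fold), Hopx (3.50-fold), Irx4 (at least 2.52-fold), Irx3 (2.52-fold) and Prox1 (2.35-fold), while Gata6 stood at 1.00 just under 2-fold and Gata4 at 0.93. Hox genes were detected for 7 of the 38 on the array, and 3 were lower: Hoxb5 (3.08-fold), Hoxa5 (2.33-fold) and Hoxa2 (2.09-fold). The Hox median was -0.82 at percentile 0.45, and -0.48 with members detected on 1 array at their bounds, which lies inside the central 95% of the random lists, taken without bounds. Of 9 detected TALE factors, a family in which only some members are partners of Hox proteins, Tgif1 (2.22-fold) and Meis2 (2.01-fold) were higher and 7 were within 2-fold, with a median of 0.036 at percentile 46.8. Other probes of Tgif1 gave 0.79 and, not well above background in total heart, 0.59. In the C/EBP family Cebpb was 2.24-fold higher and the other 3 detected members were within 2-fold, with a median of 0.086 at percentile 59.9. Of 11 detected retinoic acid genes, 2 were higher, Aldh1a1 and Aldh1a2, both also in the epicardial list, and 1 was lower, Crabp2 (2.32-fold), which binds retinoic acid in the cytosol. Their median was 0.32 at percentile 97.0.

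**Figure D4:**
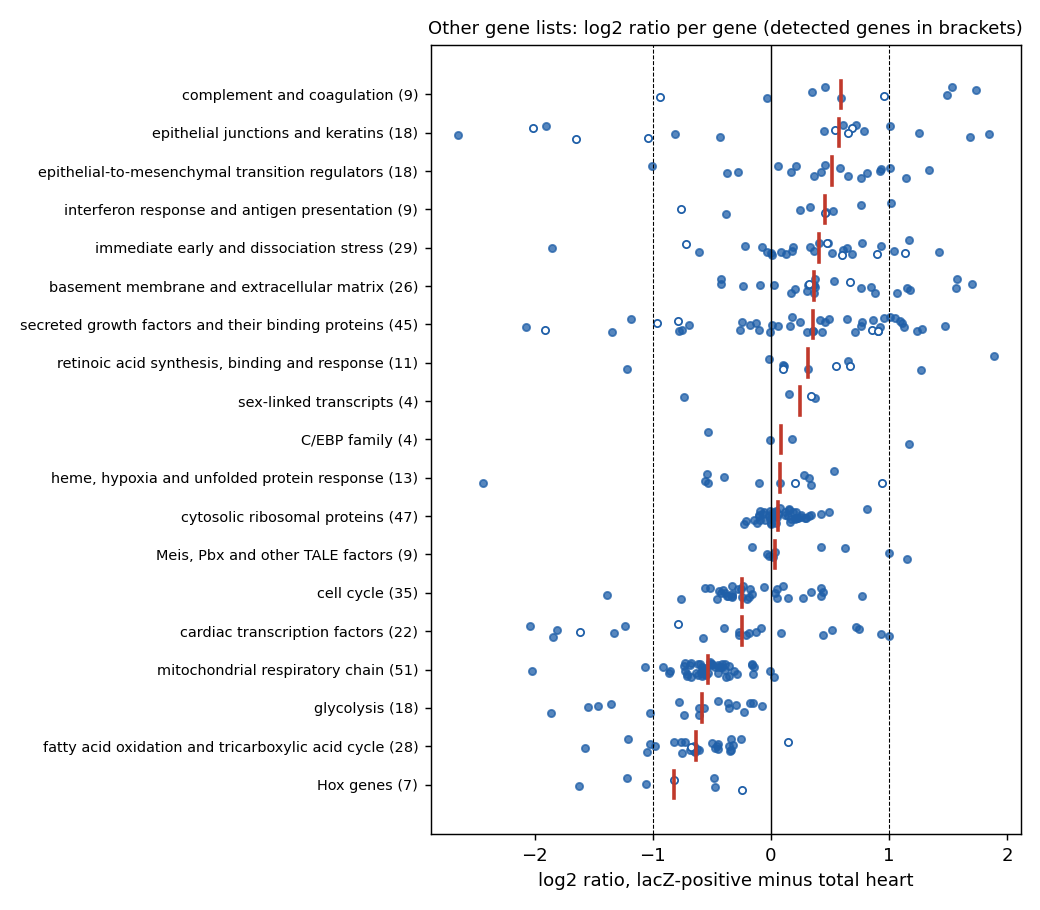
Log2 ratio, lacZ-positive minus total heart (x axis), of each detected gene in the other 19 lists, with red bars at the list medians, dashed lines at 2-fold and open circles for genes detected on 1 array only. Epithelial junction genes spread from -2.65 to 1.85, and 50 of 51 respiratory chain genes lie below 0, though the medians of cardiac transcription factors, cell cycle and ribosomal proteins change sign under another scaling.

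Epithelial genes lay on both sides. Of 18 detected genes of epithelial junctions and keratins, 4 were at least 2-fold higher, 5 were lower and 9 were within 2-fold. The median was 0.58 at percentile 99.99, and 0.26 with bounds, inside the central 95% of the random lists. The higher ones were the keratin genes Krt7, Krt14 (3.21-fold) and Krt18 (2.38-fold) and the claudin gene Cldn1 (2.01-fold). The lower ones were the claudin genes Cldn6 (6.29-fold), Cldn7 (3.73-fold) and Cldn4 (at least 2.47-fold), Krt15 (at least 2.57-fold) and Cdh1, which encodes E-cadherin (at least 1.45-fold). Of 18 detected regulators of epithelial-to-mesenchymal transition, 3 were higher, Tcf21, Twist1 and Cdh11 (2.01-fold), 1 was lower, Snai3 (2.02-fold), and 14 were within 2-fold, with a median of 0.52 at percentile 99.99. The cells were isolated by lacZ at the Tcf21 locus, so the count of Tcf21 here is not independent of the isolation. Of 26 detected genes of basement membrane and extracellular matrix, 6 were higher and 0 lower, with a median of 0.37 at percentile 99.9. The laminin gene Lama1 (3.25-fold), Fmod (2.98-fold) and the elastin gene Eln (2.22-fold) were among them.

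Secreted factors were detected for 45 genes, of which 8 were higher, 4 were lower and 33 were within 2-fold, with a median of 0.36 at percentile 99.99 and 0.24 with bounds. Igf1 was 2.78-fold higher, the lymphatic growth factor gene Vegfc 2.44-fold, Igfbp7 2.36-fold and Tgfb3 2.18-fold. Another probe of Igf1, detected on both arrays, gave 0.90. Bmp7 was 4.21-fold lower, Angpt1, which encodes a ligand for an endothelial receptor, 2.54-fold, Igfbp2 2.27-fold and Shh at least 2.18-fold. Of 9 detected complement and coagulation genes, Cfi (3.33-fold), the plasminogen activator gene Plat (2.90-fold) and Serping1 (2.82-fold) were higher and 6 were within 2-fold, with a median of 0.60 at percentile 99.6 and 0.46 with bounds. Of 9 detected interferon genes, Ifit2 (2.03-fold) was higher and 8 were within 2-fold, with a median of 0.46 at percentile 98.2, and 0.33 with bounds, inside the central 95% of the random lists. Another probe of Ifit2 gave 0.12.

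Genes of energy metabolism were lower by smaller sizes, beside the lower cardiomyocyte markers. Of 51 detected respiratory chain genes, 49 were within 2-fold and 50 were below 0, with a median of -0.53 at percentile 0. Cox7a1, the muscle form of a cytochrome oxidase subunit, was 4.07-fold lower and Cox7b 2.09-fold. Of 28 detected genes of fatty acid oxidation and the tricarboxylic acid cycle, 4 were at least 2-fold lower and 24 were within 2-fold, with a median of -0.63 at percentile 0. Cpt1b, the muscle form of the enzyme that admits fatty acids to mitochondria, was 2.97-fold lower. Of 18 detected glycolysis genes, all were below 0 and 5 were at least 2-fold lower, with a median of -0.58 at percentile 0. The muscle forms Eno3 (3.63-fold) and Pgam2 (2.55-fold) were among these 5, with Hk1, Pfkp and Pdk1. Another probe, detected on both arrays, gave -0.29 for Hk1 and -0.78 for Pfkp. With no normalization between arrays these medians were smaller, at -0.21 for the respiratory chain, -0.22 for fatty acid oxidation and the tricarboxylic acid cycle and -0.17 for glycolysis.

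General cell functions showed small shifts. Of 35 detected cell cycle genes, 34 were within 2-fold and Cdkn2c, an inhibitor of cyclin-dependent kinases, was 2.61-fold lower, with a median of -0.24 at percentile 0.03 that became 0.16 with no normalization between arrays. All 47 detected ribosomal protein genes were within 2-fold, with a median of 0.062 at percentile 47.3 that became -0.12 with scaling to the same median. Of 29 detected immediate early and stress genes, 4 were higher, 1 was lower and 24 were within 2-fold, with a median of 0.40 at percentile 100. Fos (2.69-fold), Fosl2 (2.25-fold), Fosb (at least 1.59-fold) and Klf4 (2.06-fold), all induced quickly by stimuli such as dissociation of tissue, were the higher ones, and Gadd45a was 3.61-fold lower. Another probe of Klf4, detected on both arrays, gave 0.18. Of 13 detected genes of heme, hypoxia and the unfolded protein response, 12 were within 2-fold and Trib3 was 5.43-fold lower. Their median was 0.075 at percentile 54.5 and -0.065 with bounds, so its sign is open. The 4 detected sex-linked transcripts were within 2-fold, with a median of 0.25 at percentile 75.9 and 0.11 with bounds. Xist stood at 0.16 and Eif2s3y at -0.74, while the measured ratios of the other Y-linked members were above 0.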

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

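All tests in this part were chosen after the results they bear on had been seen, in part or in full: of the 4 dim globin probes behind the first test, the ratio of 1 was known when the test was written, as were the ratios of the other erythroid genes. The conditions set for the ceiling, for bright and dim probes and for single endothelial genes were revised when their values were known. A first form of the test on bright and dim probes, limited to 5 genes whose dim probe was at least 2-fold lower, gave 5 of 5, which that limit nearly fixes in advance, and it is not used.

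A signal appeared in probes that the comparison does not use. Of 2269 detected probes without a single gene symbol in the annotation used here, 112 were at least 2-fold brighter in the lacZ-positive array than in the total heart array, and 119 were at least 2-fold dimmer. These probes are not named here and were not analysed further.

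The 4 globin genes of the erythroid list that were within 2-fold, all read by very bright probes, were close to level between the arrays. Other erythroid genes were lower, with a median of -2.73 over 12 non-globin genes. At a log2 signal of 15 or more, probes of the adult-type Hbb-bs and Hbb-bt, named after their values were seen, ran from -1.49 to -0.50. Those of the 4 level genes ran from -0.41 to 0.25. A ceiling of intensity is a candidate explanation that these data do not decide: the 4 globin probes under a log2 signal of 14 had a median ratio of -1.83 and the 13 brighter ones -0.78, but the brighter ones ran from -3.09, at a signal of 14.4, to 0.25, and 3 of the 11 at 15 or more were at least 2-fold lower. Of the dim probes, 3 belong to adult-type beta globins, whose near-identical copies may share signal, and only 1, that of Hbb-bh1 at -1.45 and near background, belongs to the 4 globin genes within 2-fold. Compression near the top of the range stays open too: among 27 genes with a probe at 14 or more and another below it, the bright probe had the smaller size in 19, or in 16 of the 24 that are not globins (66.7%), of which only 2 had a dim probe at least 2-fold lower. Whether erythroid RNA was carried over in 1 ratio for all its genes also stays open, as the dim globin probes lay 0.89 above the non-globin erythroid genes on the log2 scale, and no biological explanation, such as a different mix of red cell stages, was tested.

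Endothelial genes were close to level while epicardial genes were higher. If loss of cardiomyocytes and erythroid cells alone had set the ratios, genes of all the remaining cell types would be higher by about the same size. Against this, the epicardial median exceeded the endothelial median by 1.61 on the log2 scale, with genes detected on 1 array at their bounds. That gap restates the medians already given, and the quartiles come from the same ratios, so neither is a separate test. The leukocyte and platelet median was -0.45. The lower quartile of epicardial ratios, 1.06, lay above the upper quartile of endothelial ratios, 0.14. The bound of 1 epicardial gene, 0.12, was however under the highest endothelial ratio, 0.50. A higher share of epicardial cells, as the isolation intends, and a different level of these genes within cells both stay open and were not tested, as does how much endothelial RNA came from endothelial cells in the lacZ-positive sample.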

How the results depend on the processing

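The alternative with the brightest probe under log2 14 was chosen after seeing the data, and the others were planned. Signal over background limited the sizes: leaving background in, or adding a larger offset, shrinks ratios by construction. The numbers of higher and lower genes were 202 and 380 with no background correction, 202 and 386 with normexp without detection p-values, and 219 and 404 with the authors' processed values. With an offset of 50, 223 genes were higher and 426 lower. With no normalization between arrays they were 1020 and 381, as all genes shifted up, and at 4-fold 15 and 138. The median of the neural list became -0.61 at a detection limit of 0.05, and that of Hox genes -0.081 with no detection filter, both with more genes in the list. Over all alternatives that gave a list median, the epicardial median lay between 1.06 and 1.94, the sarcomere median between -1.63 and -1.23, the erythroid median between -2.14 and -1.78 and the fibroblast median between 0.82 and 1.31. Smaller medians varied by a larger part of their own size, though in the lists given next the shifts stayed within the limit of 1.5 times. Complement and coagulation ran from 0.098 to 0.99, interferon from 0.12 to 0.75 and retinoic acid from 0.11 to 0.75. Epithelial junctions and keratins ran from 0.17 to 0.86, and secreted factors from 0.26 to 0.73. Endothelial, cardiac factor, cell cycle and ribosomal medians changed sign with the scaling, and those of smooth muscle (-0.089 to 0.54) and of heme and hypoxia genes (-0.10 to 0.45) with other settings. Of 1312 log2 ratios of the 164 named genes under the alternatives, 93 moved by more than 1.5 times, and 29 of the genes moved under at least 1 alternative. Of ratios past 2-fold 0 changed sign. That says little, as the background and offset settings shrink ratios. Median scaling and no normalization left all 164 genes within the limit of 1.5 times, too small a shift to reverse a ratio past 2-fold.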

Other observations

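The tests on epithelial and cardiomyocyte genes in this part were chosen after the results were seen. The other values are of genes set by the naming rule.

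Further members of the lists filled out the groups. Among matrix and mesenchyme genes, Lum was 2.53-fold higher in the lacZ-positive array, Fbln2 2.45-fold, the crosslinking enzyme gene Lox 2.37-fold, Bgn 2.27-fold and Mgp, which restrains calcification, 2.09-fold. Valve and limb mesenchyme factors followed, with Meox1 2.28-fold and Msx1 2.26-fold higher. Of signalling genes, the endothelin gene Edn1 was 2.16-fold higher, Rspo1, an enhancer of Wnt signalling, 2.14-fold, and Ptn 2.07-fold. On the lower side, the red cell regulators Klf1 and Tal1 were 5.35-fold and 4.36-fold lower and the carbonic anhydrase gene Car2 6.77-fold lower. Genes of mural cells differed among themselves: the pericyte gene Rgs5 stood at 0.96 and Pdgfrb at 0.53, while Abcc9 stood at -1.93 and its channel partner Kcnj8, not well above background in total heart, was at least 1.23-fold higher.

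Probes of some genes gave different sizes. For Meis2 they ran from 1.00 to 2.19 over 3 probes, and for Fn1 from 0.057 to 1.22 over 4 probes, each detected on both arrays.

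Some epithelial genes of the kind found in endoderm, such as Cldn6 (log2 signal 8.54 in total heart and 5.89 in lacZ-positive cells) and Cldn7 (7.44 and 5.54), were lower in the lacZ-positive array, and foregut or other endodermal epithelium in the total heart sample is a candidate source, which isolation of lacZ-positive cells would remove. A list of 40 such genes, written after these values were seen, had 18 detected members with a median of -1.59, or -0.88 with bounds, and 12 of them at least 2-fold lower, against 6.45% of all detected genes. As 9 of the 18 had been named already or stood in other lists, the test used the remaining 9, chosen in place of the whole list after all its values were known. Their median was -0.063, at percentile 32.1, with 4 at least 2-fold lower and 1 higher, so that these data do not decide. Of the brighter ones, Hhex stood at 7.97 and 7.90 and Spint1 at 7.85 and 5.81, both named after their values were seen.

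The log2 ratios of 40 cardiomyocyte genes detected on both arrays ran from -3.04 to 1.07, with an SD of 0.80, which was 3.21 times the SD between probes of a gene, or 3.08 times over the 24 genes under a log2 signal of 12. Across these 40 genes, which are not independent replicates, the Spearman correlation of log2 ratio with total heart signal was 0.095.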
